A study of Mus musculus with 3 samples.

How the data were processed

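FAIRE-seq (formaldehyde-assisted isolation of regulatory elements) was applied to whole uteri of C57BL/6J mice on gestation day 4, when blastocysts are in the uterus and implantation is about to begin. Per the labels' protocols, 100 mg of frozen tissue was crosslinked in 1% formaldehyde (9 min), and the chromatin was sheared to fragments of about 300 bp on average. Phenol-chloroform extraction then kept DNA that was not held to protein in the aqueous phase, which enriches nucleosome-depleted DNA. The series holds 3 samples of 1 group, numbered 1 to 3 from their titles. The growth protocol speaks of 3 mice, whereas the design text of the series speaks of RNA from 4 mice; the 3 DNA samples were taken as the group here.

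A single peak table was analysed, which names no sample. The submitters' processing notes name FastQC, Bowtie2, HOMER and MACS2, with no versions, and the genome build GRCm38.p5. The call threshold, the use of an input control, and whether the libraries were pooled are not given in the sources used here. Per the file headers, the deposited table gives the pileup and the fold enrichment of each peak. The pileup was taken here as a coverage signal of fragments at the summit. The fold enrichment was taken as the ratio of that signal to a local background. The column names themselves do not state these definitions. The deposited table also gives the −log10 p-value and the −log10 q-value of each peak, per the file headers. Positions and widths are in bases, and the width equalled end minus start plus 1 for every peak. Columns without a name (6 of them) held no values. Library depth is unknown, so no value below carries a depth or a counting interval of its own.

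The fold enrichment was taken as the authors' score of a peak, once the columns were known and before any test. It was used only to describe, rank and compare peaks within this list. The local background of each peak was computed as (pileup + 1) / fold − 1. Because a table with no sample named gives no spread between mice, no test between samples or groups was made and no mouse was left out in turn. Peaks and genes were the units of every test, and they are not replicates: the p-values describe this list, not the variation between animals.

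Genes came from a RefSeq table of assembly GRCm38.p6, used for names and for which genes lie beside a peak; none of its coordinates is printed. After 340 genes carrying scaffold coordinates (start below 3 Mb) were left out, 49214 genes on chromosomes 1 to 19 and X remained, 21523 of them protein-coding. That exclusion was made after the first gene list results had been seen, and its effect is given below. The table holds no strand, exons or sequence. The planned promoter window around the start site therefore became 1 kb around either annotated end of a gene, and the planned 10 kb upstream became 10 kb on either side. Untranslated regions and exons were not separated. Motif content, base composition and repeat content were planned but were not analysed here, nor was agreement between samples.

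Peak centres were assigned, in this order, to a protein-coding gene end, another gene end, the inside of a protein-coding gene, the inside of another gene, or the space between genes. The shares were compared with 1000 shuffles of the peaks within their chromosomes, between the first and last gene or peak, by two-sided permutation tests with Benjamini-Hochberg adjustment. Peaks per Mb were compared with 1000 random placements in proportion to chromosome span, also two-sided. The plan left out assembly gaps, but the shuffles and the spans did not. Shuffled peaks could fall in gaps, which may raise the shuffled share between genes, and the size of this effect was not measured. Fold enrichment at gene ends and elsewhere was compared by a two-sided permutation test with 100000 resamples.

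Gene lists (16 of them) were fixed before the data were examined. Members with a peak overlapping a gene-end window were compared with all other protein-coding genes by two-sided Fisher's exact tests. A peak was counted for every gene whose window it overlapped, so a peak given for a gene may belong to a close neighbour. Members with a peak in the gene or within 10 kb were compared with 10000 random lists matched on gene length in 20 bins. Both families were adjusted by Benjamini-Hochberg over the 16 lists, at a threshold of 0.05. All other tests, including those of correlation and of the X chromosome, were two-sided as well.

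The genes named were set by rule before the data were examined: 15 uterine genes in every case; up to 4 members of each list with the highest fold at a gene end and up to 2 with no peak nearby; the 10 peaks with the highest fold; the 10 protein-coding genes with the highest gene-end fold; and the 10 with the most peaks. Of the genes this rule selects, 2 are not reported. Other genes named below were chosen after their values were seen.

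The procedures were tested on simulated data. Randomly placed peaks gave 0 of 5 location classes past the threshold. In lists of 24 genes drawn from a planted set in which 14.0% of genes had a gene-end peak, against 41.2% of the other genes, Fisher's test gave an unadjusted p under 0.05 for 76 of 100 lists. With 71.5% planted it did so for 77 of 100 lists, and with 90.5% planted for 100 of 100. Random lists of that size passed in 1 to 5 of 100 draws. These rates hold for a single list; after adjustment over 16 lists, as used here, they can only be lower or equal.

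Alternatives changed the window (500 bp, 5 kb), the rule for overlap (any base, the summit, the peak midpoint inside the window), the set of peaks, the neighbourhood of a gene and the background genes. Alternatives chosen after seeing the data were the removal of 37 peaks with a local background over 3 times the lowest, the 6207 peaks with the highest −log10 q, genes with no other protein-coding gene end within 5 kb, peaks away from gene ends, and the scaffold genes kept. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.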

Results

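Accessible chromatin was mapped by FAIRE-seq in whole uteri of 3 pregnant mice on gestation day 4, just before implantation. The uterus at this stage holds luminal and glandular epithelium, stroma, smooth muscle, vessels and immune cells, and the map mixed them all. A single list of 12413 peaks on 20 chromosomes was analysed, covering 5.86 Mb. Peaks were 217 to 3858 bp wide, with a median of 427 bp (interquartile range 307 to 583). The authors' fold enrichment over local background had a median of 5.80 and ran from 1.58 to 23.6. The list names no sample, so no value below has an error between mice, and library depth is unknown.

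The first question was where open chromatin lay relative to genes. Protein-coding gene ends held most of it: 8972 peak centres (72.3%, 95% Wilson interval 71.5 to 73.1) lay within 1 kb of an annotated end of a protein-coding gene, against 3.26% of shuffled peaks. Ends of other genes, such as long non-coding RNA genes, held 578 peaks (4.66%, against 3.29% shuffled). The interiors of protein-coding genes held 2215 peaks (17.8%, against 38.7%), and the interiors of other genes 93 (0.749%, against 6.97%). Only 555 peaks (4.47%) lay between genes, where 47.8% of shuffled peaks fell. Each of the 5 classes differed from its shuffles by a permutation test with adjusted p = 0.000999, the smallest that 1000 shuffles can give. With windows of 5 kb the ends of other genes fell below their shuffles, at 0.427 times the shuffled share. Protein-coding gene ends were assigned first, so their wider windows can take peaks from other gene ends. This value therefore does not show depletion at the ends of other genes.

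**Figure D1:**
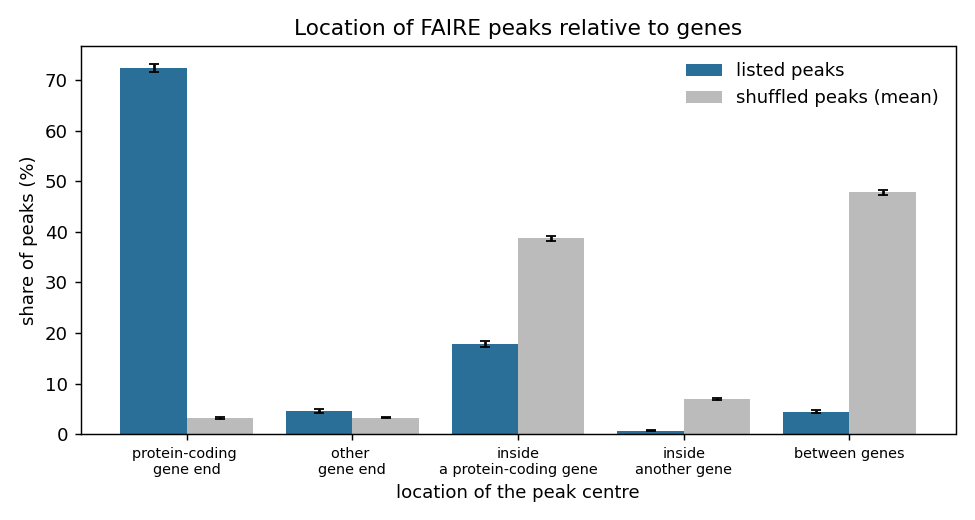
Share of peaks (vertical axis, %) by location of the peak centre (horizontal axis), for the 12413 listed peaks (blue, bars with 95% Wilson intervals) and for shuffled peaks (grey, mean and SD of 1000 shuffles). Protein-coding gene ends hold 72.3% of listed and 3.26% of shuffled peaks.

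Peaks sat close to gene ends, and long isolated genes with such a peak nearly always had it at a single end. The median distance from a summit to the nearest protein-coding gene end was 263 bp. Among 7229 protein-coding genes over 10 kb long with no other such gene end within 5 kb, 3271 had a peak at 1 end, 14 at both ends and 3944 at neither. Moving all peaks by 3 kb lowered the share at protein-coding gene ends from 72.3% to 8.35% in 1 direction and 8.27% in the other. Of all protein-coding genes, 9576 (44.5%) had a gene-end peak, compared with 12.3% of 12609 long non-coding RNA genes, 12.7% of 403 tRNA genes and 1.04% of 9762 pseudogenes. Away from protein-coding gene ends, the share of long non-coding RNA genes with a peak was 2.77% and that of tRNA genes 5.23%. None of the 374 immunoglobulin and T cell receptor V segments had a peak. Over 100 shuffles, mean shares were 2.47% of protein-coding, 2.40% of long non-coding RNA and 1.32% of tRNA genes. For pseudogenes and V segments they were 1.68% and 1.15%, so a low share there departs little from random placement. The shuffled shares cover all genes of a kind, not only those away from protein-coding gene ends.

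Peaks at protein-coding gene ends were also stronger than the others. Their median fold enrichment was 6.08 (interquartile range 4.61 to 8.05), against 5.12 (4.00 to 6.95) for the 3441 peaks elsewhere. The difference of 0.959 passed a permutation test (p = 1e-05, the smallest that 100000 resamples can give). Gene-end peaks were wider as well, with a median of 451 bp against 360 bp.

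The highest gene-end peak lay at Lars2, the mitochondrial leucyl-tRNA synthetase, at 19.97-fold (chromosome 9, 123461819 to 123462204). Its summit was inside the gene, 666 bp from the end with the higher coordinate. Without strand, that end cannot be called the start of the gene. Tmem267 (16.5), Lrrc59 (16.5), Ppib (15.9), an endoplasmic reticulum cyclophilin, and Sfr1 (15.8) came next. Dgcr8 (15.5), which processes primary microRNAs, Snx7 (15.4), Ankrd37 (15.2) and Golga5 (15.1) were also among the 10 genes with the highest gene-end fold. The 10 strongest peaks of the list lay mostly elsewhere. The first was between genes on chromosome 3 (5860341 to 5860858, 23.6-fold), 282020 bp from the nearest protein-coding gene end. Others lay inside Zc3h7a (chromosome 16, 11143904 to 11144324, 23.1-fold), Chl1 (20.3), Cdk8 (20.1), Cmss1 and Filip1l (19.5) and Aida (17.9). A peak between genes on chromosome 12 (3109748 to 3110211) reached 20.6-fold, and peaks in predicted non-coding genes on chromosomes 9 and 11 reached 19.1-fold and 17.4-fold. Sfi1, a centrosomal gene, had the most peaks, 11 in the gene or within 10 kb, followed by Gse1 (9), Tmem267 (8), Bcor, Midn and Psd (7 each) and Abr, Arhgap23, Bmi1 and Git1 (6 each). Inside Sfi1 the peaks with the highest local background had a background pileup of 127 to 132, against a median of 8.59 over all peaks, and fold enrichments of 1.58 to 2.34. These peaks are among the 37 of high background that an alternative removed. The first place of Sfi1 may depend on them, and the ranking was not repeated without them.

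Chromosomes differed in how many peaks they carried. Chromosome 11 had the most, 8.81 peaks per Mb, which was 1.82 times the value for random placement, followed by chromosome 19 (7.31 per Mb) and chromosome 17 (6.42). The X chromosome had the fewest, 1.51 per Mb or 0.314 times random placement. Only 158 of 963 X-linked protein-coding genes (16.4%) had a gene-end peak, against 9418 of 20560 autosomal genes (45.8%), an odds ratio of 0.232 by Fisher's exact test (p = 1.05e-79). In all, 10 chromosomes lay above random placement and 9 below by permutation tests adjusted over 20 chromosomes, while chromosome 10 did not pass (adjusted p = 0.907). Among the 6207 peaks with the highest fold, 8 chromosomes passed above and 6 below, and among the 6207 with the highest −log10 q, an alternative chosen after seeing the data, 7 above and 7 below. Peak density followed gene density across the 20 chromosomes, with Pearson's r = 0.845 and Spearman's rho = 0.913 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.876. Chromosomes are not independent samples of the mice.

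**Figure D2:**
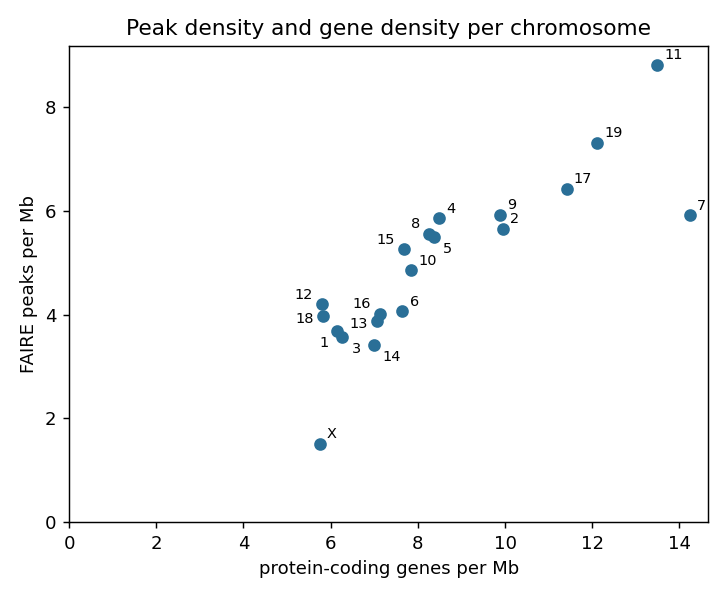
Peaks per Mb (vertical axis) against protein-coding genes per Mb (horizontal axis) for the 20 chromosomes, each point labelled with its chromosome. Chromosome 11 stands highest at 8.81 peaks per Mb and the X lowest at 1.51.

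The next question was which functional groups of genes had open chromatin at their ends. Genes of other organs, such as liver, heart, retina and testis genes, had it least: 3 of 24 (12.5%, 95% Wilson interval 4.34 to 31.0), against 44.5% of other protein-coding genes, an odds ratio of 0.178 (Fisher's exact test, adjusted p = 0.0236). The 3 were Sftpc, a lung surfactant gene (7.58-fold), Actn2 (5.12) and Ckm (3.87), and neither Alb nor Apoa1, liver genes, had a peak nearby. Sftpc and Ckm have another protein-coding gene end within 5 kb, so their peaks may belong to a neighbour. The Sftpc summit lay 874 bp outside the gene. In alternatives chosen after seeing the data, the list did not pass with the 6207 peaks with the highest −log10 q (adjusted p = 0.0528, Fisher's exact test) or among genes with no other gene end within 5 kb (1 of 10, adjusted p = 0.36). The other 15 lists did not pass the threshold. Ubiquitously expressed genes had a gene-end peak in 15 of 20 (75%, adjusted p = 0.0536, Fisher's exact test), led by Tuba1b, an alpha-tubulin gene (14.3-fold), Hnrnpk (8.15), Eef2 (7.40) and Ppia (7.39), while B2m and Gapdh had none nearby. Immune cell markers stood at 3 of 20 (adjusted p = 0.0598, Fisher's exact test): Spi1 (6.11), Ikzf1 (5.58) and Cd4 (5.32), with none near Adgre1. Spi1 and Cd4 also have another protein-coding gene end within 5 kb, and the Cd4 summit lay 909 bp outside the gene.

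Progesterone is the hormone that prepares the uterus for implantation. Of 26 progesterone-regulated uterine genes, 17 (65.4%) had a gene-end peak, with an adjusted p of 0.118 by Fisher's exact test. Fkbp4 and Fkbp5, which encode co-chaperones of steroid receptors, had the highest, at 11.4-fold (chromosome 6, 128438022 to 128438882) and 11.3-fold (chromosome 17, 28485450 to 28486388). Bmp2, a signal in decidualization, reached 7.22-fold and Areg, an epidermal growth factor family ligand, 7.12-fold, whereas Alox15 and Calca had no peak nearby. Receptivity and implantation genes also stood at 17 of 26 (adjusted p = 0.118, Fisher's exact test). They were led by Il6st, the signalling receptor chain for Lif (9.86-fold), Ror2, a Wnt receptor (8.82), Scnn1a, a sodium channel subunit (8.63), and Msx1 (7.15), and Dkk1 and Ereg had none nearby. The Scnn1a summit lay 418 bp outside the gene, with another protein-coding gene end within 5 kb, so that peak may belong to a neighbour. The result for progesterone-regulated genes depended on the processing: 22 of 26 with 5 kb windows (adjusted p = 0.00518, Fisher's exact test) and 15 of 20 among genes with no other gene end within 5 kb, an alternative chosen after seeing the data (adjusted p = 0.00361). Among the 6207 peaks with the highest fold it was 7 of 26 (26.9%, adjusted p = 1.00, Fisher's exact test), and among the 6207 with the highest −log10 q, also chosen after seeing the data, 6 of 26 (23.1%, adjusted p = 0.827). With fewer peaks the share of the other genes falls as well, so these shares cannot be compared with those over all peaks.

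Oestrogen-regulated genes had gene-end peaks in 5 of 22, which did not pass the threshold (adjusted p = 0.118, Fisher's exact test). The strongest were at Gadd45g (7.24-fold), Egr1 (5.69), Inhbb (5.62) and Mad2l1 (3.87), and C3 and Clca1 had none nearby. Decidualization genes stood at 10 of 24 (adjusted p = 0.840, Fisher's exact test), with Ctsl, a lysosomal protease, at 9.03-fold, Bmpr1a at 7.91 and Bmpr2 at 7.40, and none near Alpl or Aoc1. Immediate early and stress genes stood at 12 of 18 (adjusted p = 0.125, Fisher's exact test), led by Dusp1 (7.68-fold), Klf2 (7.42) and Jund (6.05). Hox genes stood at 13 of 39 (adjusted p = 0.225, Fisher's exact test).

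Markers of the cell types in the uterus did not pass the threshold at gene ends. Epithelial markers had peaks in 6 of 24, among them Epcam (6.53-fold), Wnt11 (5.63), Cdh1 (4.75) and Wnt7a (4.75), with none near Cldn3 or Cldn4. Stromal markers stood at 5 of 20, led by Fn1, fibronectin (8.26), Twist1 (7.45) and Twist2 (5.12), with none near the collagen genes Col1a2 and Col3a1. Smooth muscle markers stood at 9 of 18, with Mylk, myosin light chain kinase (9.69), Tpm2 (7.66), Pgm5 (7.25) and Tpm1 (4.71), and none near Acta2 or Gja1. Endothelial markers stood at 4 of 17: Flt1 (6.12), Sox7 (4.62), Erg (4.25) and Sox18 (3.62), with none near Cdh5 or Cldn5. Blastocyst markers stood at 3 of 15: Tead4 (6.13), Eomes (4.83) and Klf4 (3.14), with none near Cdx2 or Dppa3. Neuronal and glial markers stood at 5 of 23, led by Map2, a microtubule-associated protein gene (12.8), Tubb3 (5.50), Grin1 (4.25) and Mbp (3.75), with none near Aqp4 or Camk2a. Neuropeptide and hormone signalling genes stood at 8 of 29, led by Crh, corticotropin-releasing hormone (7.12), Kiss1r (6.22), Penk (5.96) and Oxt, oxytocin (5.62), with none near Drd2 or Esr2. Adjusted p over these 7 lists ran from 0.118 to 0.687 by Fisher's exact tests. Which lists passed depended on the window, the peaks and the genes used: over the alternatives, from 0 to 4 lists passed above the other genes and from 0 to 5 below.

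**Figure D3:**
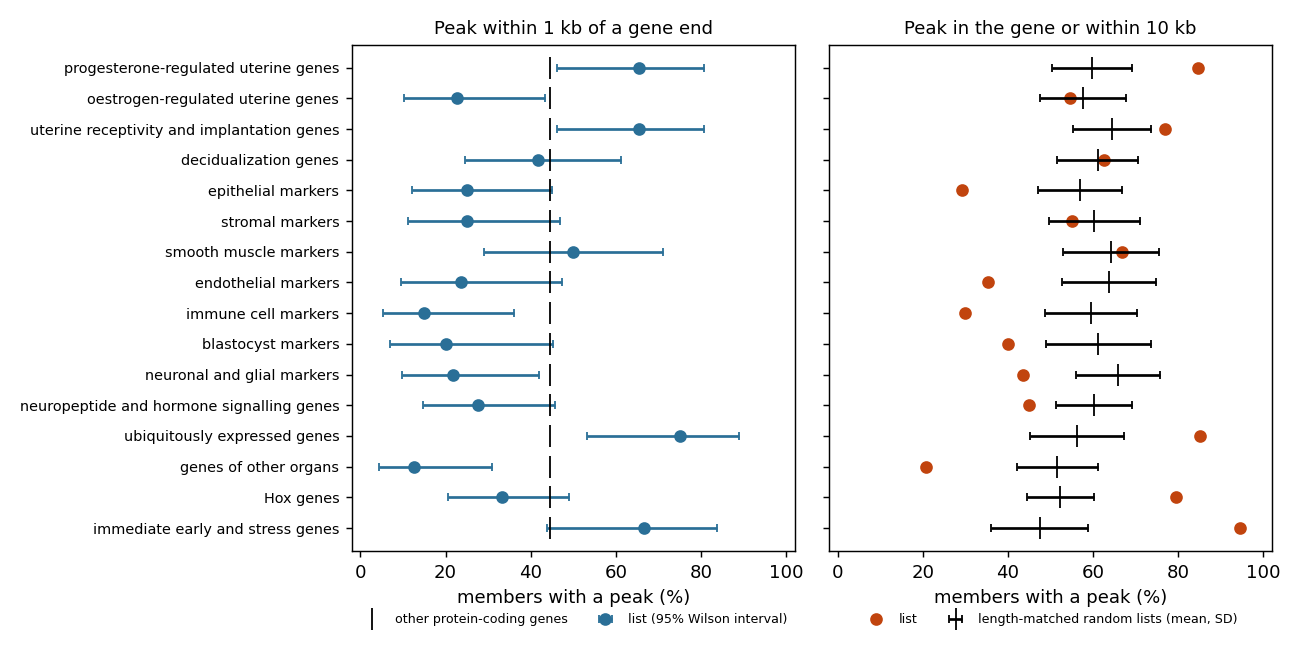
Share of members with a peak (horizontal axes, %) for the 16 gene lists (listed down the vertical axis). Left, peaks within 1 kb of a gene end, with 95% Wilson intervals and the share of other protein-coding genes as a tick. Right, peaks in the gene or within 10 kb, with the mean and SD of length-matched random lists in black. Genes of other organs stand at 12.5% on the left and 20.8% on the right, and immediate early and stress genes at 94.4% on the right.

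When peaks in the gene or within 10 kb were counted, more lists separated from length-matched random lists. Immediate early and stress genes, which respond within minutes to stimuli, had a peak in 17 of 18 (94.4%, against 47.4% in random lists; permutation test, adjusted p = 0.0016), Hspa1b being the exception. By the same permutation tests, Hox genes had one in 31 of 39 (79.5% against 52.3%, adjusted p = 0.004), progesterone-regulated genes in 22 of 26 (84.6% against 59.7%, adjusted p = 0.0265) and ubiquitously expressed genes in 17 of 20 (85.0% against 56.3%, adjusted p = 0.0265). Below random lists in these permutation tests lay genes of other organs with 5 of 24 (20.8% against 51.6%, adjusted p = 0.0064), epithelial markers with 7 of 24 (29.2% against 56.9%, adjusted p = 0.0212), immune cell markers with 6 of 20 (30.0% against 59.4%, adjusted p = 0.0265) and endothelial markers with 6 of 17 (35.3% against 63.8%, adjusted p = 0.028). Neuronal and glial markers, with 10 of 23 (43.5% against 65.8%), passed narrowly (permutation test, adjusted p = 0.0491) and did not pass when the scaffold genes, left out after list results had been seen, were kept (adjusted p = 0.0524). Among the 6207 peaks with the highest fold, permutation tests no longer separated progesterone-regulated genes (12 of 26, adjusted p = 0.496) or ubiquitous genes (11 of 20, adjusted p = 0.0859), and Hox genes turned to below random lists (3 of 39, adjusted p = 0.0272). With 50 kb on either side, none of the 5 lists below random lists passed the threshold any longer, although all 5 kept their direction, and neither did progesterone-regulated genes (permutation test, adjusted p = 0.103).

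The other 7 lists did not separate from random lists by these permutation tests. Receptivity genes had a peak in 20 of 26 (permutation test, adjusted p = 0.279), decidualization genes in 15 of 24 (1.00), oestrogen-regulated genes in 12 of 22 (0.946), and stromal markers in 11 of 20 (0.788). Smooth muscle markers had one in 12 of 18 (1.00), blastocyst markers in 6 of 15 (0.167) and neuropeptide genes in 13 of 29 (0.181).

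Hox genes pattern the reproductive tract, and their open chromatin was many weak peaks in clusters. The Hoxd cluster held 10 peaks, or 10.3 per 100 kb, and the Hoxa cluster 7, or 6.63 per 100 kb. Hoxb held 5 (2.87 per 100 kb) and Hoxc 2 (1.73 per 100 kb). The strongest gene-end peaks lay at Hoxd3 (6.45-fold), Hoxd1 (5.77), Hoxb2 (5.66) and Hoxd8 (5.47), while Hoxa13 and Hoxb1 had none nearby. Hoxa10 and Hoxa11, needed for implantation, shared peaks of 3.65-fold (chromosome 6, 52245069 to 52245497, inside Hoxa11) and 3.61-fold (52234419 to 52234774, inside Hoxa10). Because neighbouring Hox genes share peaks, their count of 31 is not 31 separate observations.

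Steroid receptor genes and their partners differed. Pgr, the progesterone receptor, had 1 peak inside the gene, 2914 bp from its end (chromosome 9, 8901604 to 8902147, 5.05-fold), while Esr1, the oestrogen receptor, Prlr, the prolactin receptor, and Foxa2, a gland transcription factor, had none in the gene or within 10 kb. Lif, the cytokine required for implantation, had a single strong peak (chromosome 11, 4266575 to 4266967, 8.99-fold), 5740 bp from its nearest end and inside the gene. Nr2f2, a stromal nuclear receptor, had 3 peaks, the strongest inside the gene at 10.4-fold (chromosome 7, 70361685 to 70362114). Gata2 had 4, with 3.65-fold at its end and up to 7.29-fold 4750 bp inside (chromosome 6, 88198464 to 88198812). Msx1 reached 7.15-fold at its end (chromosome 5, 37824339 to 37824828) and Bmp2 7.22-fold (chromosome 2, 133551998 to 133552485). Peaks at Wnt4 (4.74), Hand2 (4.29 at its end, 3 peaks), Oxtr, the oxytocin receptor (4.07, inside the gene), and Ihh (3.85, 2 peaks) were weaker than the list's median of 5.80. A missing peak shows only that none was listed, since depth and call threshold are unknown.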

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

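The main limits are that 1 list without replicates was analysed, that depth is unknown, and that lists of 15 to 39 genes leave wide intervals. The 5 location classes kept direction and side of the threshold under all alternatives run except 1. Protein-coding gene ends ranged from 6.36 to 36.5 times the shuffled share. With 5 kb windows, other gene ends turned to 0.427 times, protein-coding gene ends being assigned first. Chromosome 11 stayed at 1.68 to 1.83 times random placement and the X at 0.168 to 0.315. The fold difference at gene ends stayed at 0.812 to 1.12. Removing the 37 peaks of high background, chosen after seeing the data, changed no call or direction. The peak count was 6207 by construction in the stronger subsets by fold or −log10 q, with median widths of 524 and 533 bp, and merging peaks within 500 bp gave 462 bp. Other than by construction, the cause of the changes below was not tested. Percentages of lists below are shares of the list alone. The share of the genes or random lists compared can change with the setting too, and is not printed.

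At gene ends, 500 bp windows called 2 lists below, adding immune markers (5.00%). Windows of 5 kb called 4 above: progesterone-regulated (84.6%), ubiquitous (80.0%), immediate early (83.3%) and Hox genes (71.8%, reversed). Length matching called 2 above, ubiquitous (75%) and immediate early genes (66.7%), and 3 below, adding immune (15%) and neuronal markers (21.7%). The midpoint rule called 1 above, ubiquitous genes (75%). The highest-fold peaks called 5 below, adding oestrogen-regulated genes (4.55%), epithelial (4.17%) and neuronal markers (4.35%) and Hox genes (2.56%). Chosen after seeing the data, the highest −log10 q called 2 below, immune markers (0%) and Hox genes (5.13%), and no longer other organs (4.17%, adjusted p = 0.0528, Fisher's exact test). Genes without close neighbours, also added, gave 1 above, progesterone-regulated genes (75%), and 0 below, with other organs at 10.0% of fewer genes.

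Near genes, the highest-fold peaks called 1 list above, losing progesterone-regulated (46.2%) and ubiquitous genes (55.0%), with Hox genes reversed (7.69%) and neuropeptide genes below (13.8%). The gene body alone called 2 below, losing epithelial (25%), endothelial (35.3%) and neuronal markers (34.8%), and lost Hox genes (53.8%). With 50 kb on either side 0 were called below, with directions kept: epithelial (62.5%), endothelial (70.6%), immune (55.0%) and neuronal markers (56.5%), other organs (54.2%), and progesterone-regulated genes (92.3%) lost their calls. Assignment to the nearest end called 2 below, losing epithelial (29.2%), endothelial (35.3%) and neuronal markers (43.5%), and added receptivity genes above (76.9%).

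Of the alternatives chosen after seeing the data, the highest −log10 q called 1 list above and 2 below. It lost progesterone-regulated (46.2%), ubiquitous (55.0%), epithelial (12.5%), endothelial (11.8%), neuronal (17.4%) and other-organ genes (12.5%), reversed Hox genes (12.8%) and added neuropeptide genes below (10.3%). Distal peaks alone called 0 below: epithelial (8.33%), endothelial (11.8%), immune (0%) and other-organ genes (0%) were lost, and oestrogen-regulated (31.8%), stromal (35.0%), neuronal (17.4%) and ubiquitous genes (10.0%) changed direction with a call on either side. Blastocyst (20%) and neuropeptide genes (17.2%) changed direction without a call. Keeping the scaffold genes lost neuronal markers (43.5%, permutation test, adjusted p = 0.0524). Contigs, chrM and chrY held no listed peaks.

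Not run, for want of sequence or of values per sample, were matching on CpG content, leaving out repeat-rich peaks, all motif and sequence alternatives, and leaving out each mouse in turn. No paired analysis was possible because there is 1 group and the list carries no replicate numbers.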

Other observations

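Gene families and the tests of distal peaks, the X chromosome content and the background of the strongest peaks were chosen after the first results had been seen; the families were set from symbol patterns before family values were computed, although some members stand in lists whose results had been seen.

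Several families stood above the other protein-coding genes in gene-end peaks. Mitochondrial ribosomal protein genes had one in 57 of 78 (73.1%, Fisher's exact test, adjusted p = 1.53e-06), led by Mrps16 (12.1-fold), and splicing factor genes in 25 of 32 (78.1%, adjusted p = 0.000261), led by Srsf5 (11.9). Cytosolic ribosomal protein genes had one in 51 of 77 (Fisher's exact test, adjusted p = 0.000261), with proteasome and respiratory complex I genes at 28 of 40 each (adjusted p = 0.00215). Kruppel-like factor genes, among them Klf11 (10.53) and Klf16 (10.3), stood at 14 of 17 (82.4%, Fisher's exact test, adjusted p = 0.00351), and Sox genes at 13 of 19 (adjusted p = 0.0494). All of these are Fisher's exact tests over 20 families, against about 44.4% of other genes.

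A further set of families stood below. Olfactory receptor genes had a gene-end peak in 1 of 1109 and vomeronasal receptor genes in 2 of 350, with adjusted p = 2.36e-290 and 1.89e-85 by Fisher's exact tests. Keratin genes had one in 2 of 53 (Krt10 at 12.9-fold and Krt1 at 7.87), interleukin genes in 1 of 33 (Il17d), chemokine genes in 3 of 36 (Ccl25, Cxcl12 and Cxcl14), claudin genes in 4 of 35, cytochrome P450 genes in 9 of 99 and collagen genes in 12 of 44 (Fisher's exact test, adjusted p = 0.0301, the highest of these). Histone genes stood below at gene ends (19 of 67, 28.4%, Fisher's exact test, adjusted p = 0.0132), in a test not matched on gene length. Within 10 kb they stood above length-matched lists (35 of 67, 52.2% against 12.2%, adjusted p = 0.0002 by permutation). A gene-end peak is also a peak within 10 kb, so length-matched lists had gene-end peaks in at most 12.2% on average. The histone share of 28.4% lay above that, so these genes stood below only against genes of all lengths. Which genes fill the length-matched lists was not examined, so gene length is not shown to be the reason. Histone genes lie in clusters and share peaks. Members of any family that lie side by side are not separate observations, so the p-values of such families are too small. Zinc finger, Wnt, integrin and fibroblast growth factor genes did not pass either test.

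Distal peaks, those overlapping no window of 1 kb around a protein-coding gene end, numbered 3184, with a median fold of 5.12. Among list members the strongest stood at Nr2f2 (10.4-fold), Tpm1 (9.83), Nr4a1 (9.54), Fosb (9.41), Lif (8.99), Klf15 (8.77), Sgk1 (8.08), Actb (8.03) and Lifr (7.90). Nr2f2, Lif, Klf15, Sgk1 and, lower down, Per1 (6.06) were picked from all of these as genes known to respond to steroid hormones. Distal here means only outside the 1 kb windows. These summits lay 1492 bp (Klf15), 2003 bp (Per1), 4888 bp (Nr2f2), 5330 bp (Sgk1) and 5740 bp (Lif) from the nearest gene end. Over the 16 lists, distal peaks lay above length-matched random lists for Hox genes (20 of 39), immediate early genes (9 of 18) and progesterone-regulated genes (11 of 26, 42.3% against 12.8%), each with adjusted p = 0.000533 by permutation, and also for stromal markers (7 of 20, 0.0296) and oestrogen-regulated genes (7 of 22, 0.0384). The 20 Hox genes shared 11 distinct distal peaks, so they are not separate observations and the p for that list is too small. The 7 stromal markers include Hoxa10, Hoxa11, Hoxd10 and Hoxd11, which share distal peaks, so the stromal p is too small as well. Hoxa10 and Hoxa11 also count among the 11 progesterone-regulated genes. The oestrogen-regulated genes with a distal peak include Fos, Jun and Egr1, which also stand in the immediate early list. A separate list of 24 glucocorticoid or progestin induced genes, written down before their peaks were looked up, had a distal peak in 9 (37.5%, against 11.1% in random lists, permutation p = 0.0009), including Sesn1 (10.8-fold), Map3k6 (7.94) and Errfi1 (6.49). A hypothesis is that distal open sites at such genes may be steroid response elements. However, Hox genes (51.3%) and immediate early genes (50%) had higher shares with a distal peak, so the excess is not particular to steroid-induced genes. Receptor binding was not tested and sequence was not analysed here; start sites missing from the gene table remain open as another explanation, and the separate list also lay above other genes in gene-end peaks (16 of 24, p = 0.0382, Fisher's exact test).

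On the X chromosome, gene-end peaks were weaker as well as fewer. Their median fold of 5.27 over 150 peaks lay below those of all 19 autosomes (5.41 to 6.45) and below the autosomal 6.10 (permutation p = 0.0023). A higher local background on the X is argued against, since the pileup was lower (42 against 59, permutation p = 0.0001). The X median background of 7.002, against 8.72, was also within rounding of the lowest value in the list, as was the background of 2155 peaks. For the share of genes with a peak, a different kind of gene on the X is argued against as the only reason, within broadly used genes. Of members of 5 broadly used families and the ubiquitous list, 1 of 9 on the X (Hprt) and 200 of 275 on autosomes had one (Fisher's exact test, p = 0.000283). However, 2 of those 9 and the totals of the families had been seen beforehand. Whether gene content adds to the gap over all X-linked genes was not tested. A hypothesis is that the inactive X copy of each female cell may lower the peaks; its test was whether the X median fold lay below that of every autosome, and at 5.27 it did. Lower coverage of the X for another reason would pass the same test, since the background is at its floor, and remains open: neither reads by allele nor an input library were analysed here. A different mix of genes on the X could pass it too, since gene content was examined only for the share of genes with a peak, not for fold.

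The strongest peaks lay at protein-coding gene ends less often than the next ones. Of the 20 with the highest fold, 8 (40.0%) did so, against 164 of 200 (82.0%) of those ranked 21 to 220 (odds ratio 0.146, Fisher's exact test, p = 0.000108). High-copy sequence, such as repeats or nuclear copies of mitochondrial DNA that collect reads from elsewhere, is a possible explanation that this share leaves standing; sequence was not analysed here. Their median background of 12.1 also lay above the 90th percentile of all peaks (11.8), but this is not particular to them: the median background rose with fold from 7.62 in the weakest peaks to 11 in those ranked 21 to 220. No biological explanation was tested.

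Peaks with an extreme local background formed a few groups. In all, 30 peaks had a background over 10 times the lowest value, the highest on chromosome 17 (39843086 to 39846777, 214). Others lay near the start of chromosome 9, such as 3000035 to 3001851 (113), inside Sfi1, and on chromosome 14 (19415673 to 19419530, 110).

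For gene-end lists, gene length is argued against as the reason why genes of other organs stood below, since the adjusted p was 0.0243 against length-matched lists. Peaks of neighbouring gene ends cannot be told apart from the list's own: with no other gene end within 5 kb only 10 members were left, 1 with a peak (odds ratio 0.214 against 0.178 with all members, adjusted p = 0.36, Fisher's exact test), and even 0 of 10 would have given an adjusted p of 0.103.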
